A study of Mus musculus with 82 samples.

How the data were processed

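RNA was measured by poly-A RNA sequencing (per the labels, 200 ng of total RNA and 100-base paired-end reads) in 82 mouse samples that the labels place in 22 groups. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.0, featureCounts 2.0.1, kallisto 0.46.0 and edgeR 3.12, and the mouse build GRCm39 (mm39), without saying which step each served. Labels describe the TIRR KO as a germline deletion of the first exons, made by crossing a floxed allele to EIIa-Cre, and the P53KO control group as a pool of TIRR wild-type and heterozygous mice. They state that the metabolic studies used male C57Bl6 littermates on normal chow.

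For hypothalamus, liver and PGAT of cohort 2, the deposited values are estimated counts per transcript, and per the file headers these come from kallisto. The same files hold TPM, which per the file headers is scaled over all transcripts of a library. For MEFs the deposited values are whole-number counts per Entrez gene ID, with no normalisation. For PGAT of cohort 1 and BAT, the deposited counts are totals per assignment category of each library, as featureCounts writes them, with no genes. Their unit (fragments or alignments) is not stated, and reads that map to several places may be counted several times. The deposited series table for MEFs holds a signal, the per-library counts times 1 factor per library, under upper-case gene names (99.62 to 99.74% of shared names lie within a ratio of 0.01 of the median factor). The series tables of estimated counts and TPM repeat the per-library values for 98.82 to 99.36% of shared names within 0.01 on the log2 scale. These tables were used only for that check.

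Each kallisto file listed 142238 transcripts, of which 141700 matched GENCODE M21 by ID without version. Unmatched transcripts held at most 0.322% of estimated counts. Estimated counts were summed to 55408 genes and rounded to whole numbers. GENCODE M21 belongs to an older build than the one the notes name, so it served only for names. In MEFs, 25275 of the IDs in the 9 long files had a symbol, and 25054 IDs were shared by all 12 libraries. Chromosome order for the check of the 3 short MEF files came from the RefSeq gene table.

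Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr on low counts, TMM normalisation, and the quasi-likelihood F test with a Benjamini-Hochberg threshold of 0.05. Each tissue was fitted on its own 6 libraries, and the tissue differences on all 18 with a term per tissue and genotype. The MEF contrasts and the interaction were fitted in 1 model of 4 groups. The fit of all 18 gives each gene 1 spread for the 3 tissues. Fitted alone, they had biological coefficients of variation of 0.102 (hypothalamus), 0.291 (PGAT) and 0.188 (liver). Errors of differences that involve PGAT may therefore be understated. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. In MEFs this was undefined for some genes with an F statistic that was not positive, none of which is named. The fit planned before the data were examined used all 12 MEF libraries. The fit of 9 was chosen after seeing the data, because 3 files listed other gene IDs and their values did not follow the others. Leaving out 1 more library there leaves some genotypes with 1 library, which is assumed to vary like the other groups. Shares of assigned reads were compared by exact two-sided permutation tests with Python 3.11.15, with adjustment over 6 comparisons.

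Gene lists, 51 in all, were fixed before the data were examined and tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one, with adjustment over the lists of a comparison. Lists with fewer than 4 measured members were not tested. No list call held with an estimated correlation in any comparison. Members were counted over all genes and adjusted over the list alone. Overlaps were tested with Fisher's exact test on genes tested in both comparisons.

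Genes were named by a rule fixed before the data were examined. It took Nudt16l1, Trp53 and Trp53bp1 everywhere, then the 10 genes that rose and the 10 that fell most among calls with a mean log2 CPM of at least 1, an approved symbol and no overlap between groups, then up to 4 members with the smallest p from each list described. Where fewer than 5 genes were called, all were named. The rule was departed from after values were seen: all calls were also named in hypothalamus (7) and in the tissue differences with 5 calls, symbols of placeholder loci were left out, and the criterion of no overlap was not applied to differences of effects. In MEFs the rule was applied to the fit of 9 libraries. Genes named as list members beyond the 4 smallest p, Nudt16l1 transcripts and sex-linked genes were likewise chosen after their values were seen. Folds against a group with no counts used a floor of 3 counts over the group, and floors and intervals cover counting error only.

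The edgeR, DESeq2 1.42.0 and limma scripts were tested on simulated counts drawn from the real means, library sizes and spread, with 200 genes changed by 1.5-, 2- or 4-fold. At 1.5-, 2- and 4-fold, edgeR recovered 65.7, 90.6 and 98.6% in hypothalamus, 2.9, 23 and 89.9% in PGAT, 10, 59.7 and 98.5% in liver, and 84.2, 92.4 and 98.7% for TIRR KO against fl/fl in the 9 MEF libraries. For the difference between liver and hypothalamus it recovered 4.4, 25 and 70.8%. Unchanged genes called numbered 10, 12 and 17 with edgeR and 23, 52 and 41 with DESeq2 in hypothalamus, PGAT and liver, so DESeq2 made more false calls in the tissue simulations. For TIRR KO against fl/fl in the 9 MEF libraries DESeq2 made fewer, 12 against 17 with edgeR. The list test called 5 of 5 shifted lists and 0 of the other 35 in data simulated for hypothalamus. Simulated genes varied independently of each other, while the oxidative phosphorylation list had an estimated correlation of 0.703 in hypothalamus. The simulation therefore cannot tell how often lists of correlated genes are called falsely. Both genotypes were also given the same spread per gene, which the real libraries need not share. The recovered shares may therefore not hold for the real libraries.

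Alternatives set before the data were examined were DESeq2 size factors in edgeR, no filter on low counts, DESeq2's Wald test, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with TPM of at least 1, a fit of only the groups compared, a replicate block, an overlap threshold of 0.1, the share of aligned reads only, and leaving out each replicate. Replicate numbers did not pair samples within a comparison. Codes in the library titles that the 3 tissues share were taken to mark the same animal. The code of hypothalamus KO replicate 2 is spelled differently from that in PGAT and liver, and its match was assumed. The animal block is therefore given beside the tissue differences. Same-coded libraries deviated together by a median r of only 0.019 across tissues (18 pairs, -0.076 to 0.087). Figures were drawn with matplotlib 3.10.9.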

Results

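The series sequenced RNA from 82 mouse samples in 22 groups to ask how loss of TIRR, a protein that binds 53BP1 and limits its action on p53, changes gene expression in metabolic tissues and in fibroblasts with and without p53. TIRR is encoded by Nudt16l1. Hypothalamus, liver and perigonadal adipose tissue (PGAT) of cohort 2 were each profiled in 3 wild-type (WT) and 3 TIRR knockout (KO) male mice, 18 libraries in all. Mouse embryonic fibroblasts (MEFs), isolated at embryonic day 13.5 and immortalised by passaging, were profiled as 12 libraries, 3 each of TIRR fl/fl, TIRR KO, P53 KO and P53 KO TIRR KO. The other 52 samples, 26 of PGAT from cohort 1 and 26 of brown adipose tissue (BAT), are represented in the files read here only by totals of reads per assignment category, so no gene was measured in them.

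Depth was even within each tissue. Estimated counts per library (in M, mega) ranged from 22.94 to 24.22 M in hypothalamus, from 23.61 to 24.86 M in PGAT of cohort 2 and from 24.58 to 24.89 M in liver. In MEFs, 9 libraries held 33.65 to 35.37 M counts. The other 3 (TIRR fl/fl replicate 1, P53 KO replicate 3 and TIRR KO replicate 3) held 4.33 to 4.42 M counts, listed a different set of gene IDs, and their gene values correlated with those of the other 9 at Pearson r between -0.111 and -0.078 across genes, which are not independent replicates. The fit planned for MEFs used all 12 libraries. The fit on 9 libraries was chosen after seeing the data, and both are given.

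Nudt16l1 (ENSMUSG00000022516) was the targeted gene and was lower in every TIRR KO library of the 3 tissues and of the 9 MEF libraries described above than in every library of its control group. In hypothalamus it fell from 30.1 ± 2.69 to 13.4 ± 0.653 counts per M (CPM; mean ± SD, n = 3 and 3; log2 fold change -1.17, SE 0.091; edgeR adjusted p = 0.00225). In PGAT of cohort 2 it fell from a mean of 28.4 to 5.37 ± 0.912 CPM (log2 fold change -2.40, SE 0.179; edgeR adjusted p = 0.0493). In liver the means were 8.99 ± 0.6 CPM in WT and 4.78 ± 1.17 CPM in KO, and the difference did not pass over all genes (log2 fold change -0.91, SE 0.188; edgeR adjusted p = 0.471). In the 9 MEF libraries it fell from 25.3 ± 2.78 CPM in TIRR fl/fl (n = 2) to 7.82 ± 0.148 CPM in TIRR KO (n = 2; edgeR adjusted p = 8.19e-10). It also fell from 24.6 ± 0.903 CPM in P53 KO (n = 2) to 8.16 ± 0.606 CPM in P53 KO TIRR KO (n = 3; edgeR adjusted p = 2.07e-10).

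Of the Nudt16l1 transcripts, ENSMUST00000229961.1 held 91.5 to 131 estimated counts per library in WT hypothalamus and at most 6.79 in KO. It held 88.6 to 111 counts in WT PGAT and 0 in KO PGAT, and 26.5 to 37.5 counts in WT liver and 0 in KO liver. ENSMUST00000230931.1 kept 119 to 192 counts in KO hypothalamus against 312 to 419 in WT. ENSMUST00000230224.1 was higher in KO, with 47 to 65 counts against 17.56 to 44.23 in hypothalamus and 15 to 24 against 6.51 to 16.13 in liver, and held 10 to 35 against 24.25 to 35.41 in PGAT. Per the labels, the deletion removes only the first exons, so counts that remained on Nudt16l1 do not speak against the genotype. The plot of Nudt16l1 per library shows that the KO and control libraries did not overlap in any of the 3 tissues or in MEFs.

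**Figure D1:**
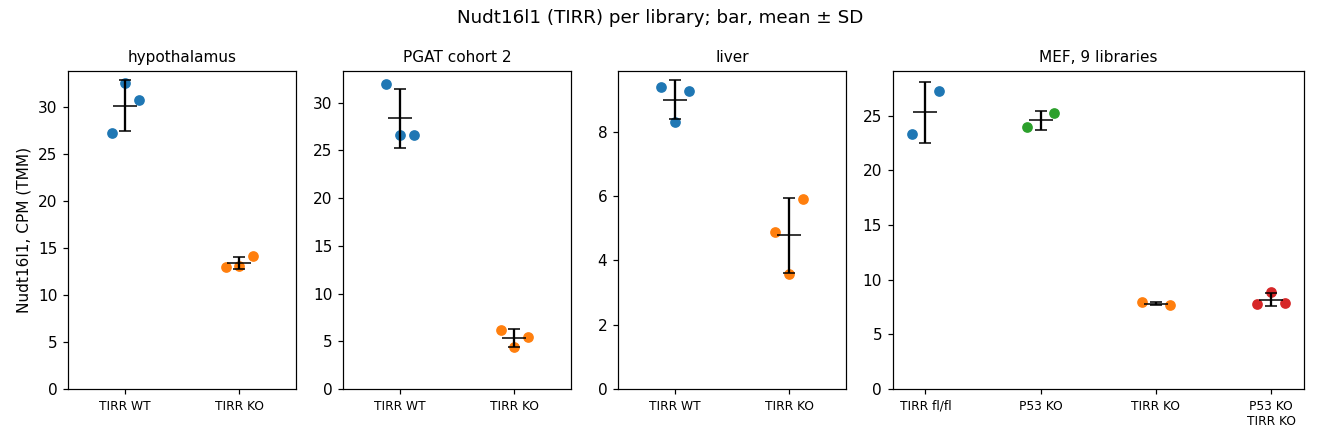
Nudt16l1 in CPM (TMM-normalised) per library in hypothalamus, PGAT of cohort 2, liver and the 9 MEF libraries; each point is 1 library and the bars give mean ± SD. KO libraries lie below the controls in every panel, for example at 13.4 against 30.1 CPM in hypothalamus.

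In hypothalamus, the comparison of TIRR KO with WT addressed whether loss of TIRR alters the region that controls feeding and energy expenditure. The gene with the smallest p was mt-Nd3, a mitochondrially encoded subunit of respiratory complex I, which rose from 166 ± 28.9 to 893 ± 125 CPM (log2 fold change 2.43, SE 0.145; edgeR adjusted p = 0.000667). Gm28438, a pseudogene with nearly the same sequence as mt-Nd3, fell by 6.54 on the log2 scale (SE 0.749; edgeR adjusted p = 0.0368), so the split of reads between these 2 genes is uncertain. Cd59a, which protects cells from the complement membrane attack complex, fell from 41.4 ± 3.14 to 17.1 ± 3.18 CPM (edgeR adjusted p = 0.0124). Sh2d1a, a signalling adaptor of T and NK cells, fell from 3.97 ± 0.899 to 0.932 ± 0.205 CPM (edgeR adjusted p = 0.0405). The predicted gene Gm15446 fell by 3.73 (edgeR adjusted p = 0.00225) and Pisd-ps2, a pseudogene of the mitochondrial enzyme Pisd, rose by 1.33 on the log2 scale (edgeR adjusted p = 0.0405).

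Genes of oxidative phosphorylation encoded in the nucleus were shifted downward as a group in KO hypothalamus, with a median log2 fold change of -0.195 over 37 genes. None passed over all genes and 21 passed adjusted over the list alone, among them Ndufa4 (-0.34, SE 0.072), Ndufs3 (-0.25, SE 0.062), Ndufb8 (-0.29, SE 0.071) and Cox6c (-0.29, SE 0.075), which are subunits of complexes I and IV (camera adjusted p = 3.23e-14, and adjusted p = 0.908 with an estimated correlation). Immediate early genes, which respond within minutes to neuronal activity or handling, were also shifted downward over 12 genes (camera adjusted p = 6.31e-05, and adjusted p = 0.908 with an estimated correlation). Adjusted over the list alone, 5 of them passed, including Junb (-0.94, SE 0.163), Fos (-1.09, SE 0.198), Egr2 (-1.60, SE 0.369) and Arc (-0.54, SE 0.127). Cytosolic ribosomal protein genes had a median of -0.164 over 26 genes, of which Rps9 (-0.37, SE 0.083) passed adjusted over the list alone (camera adjusted p = 6.31e-05, and adjusted p = 0.908 with an estimated correlation). Marker lists moved by about as much, with medians of -0.183 for oligodendrocytes, -0.194 for microglia, -0.331 for thalamus and neighbouring forebrain and 0.285 for extracellular matrix, so these shifts were not separated from a difference in cell type or in the region dissected. KO replicate 3 stood apart from the other KO libraries, with a chi-square per degree of freedom of 20.001 and 20.101 against 6.761 between those.

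Trp53, the gene of p53, was at 18.8 ± 1.17 CPM in KO and 18.8 ± 1.56 CPM in WT hypothalamus (log2 fold change -0.002; edgeR adjusted p = 0.993), and Trp53bp1, which encodes 53BP1, had a log2 fold change of 0.12 (edgeR adjusted p = 0.489). No p53 target gene passed among 47, over all genes or adjusted over the list alone, and the list had a median of -0.031 (camera adjusted p = 0.69). Of 24 hypothalamic feeding and neuroendocrine genes none passed, with Lepr, the leptin receptor, at 0.70 (SE 0.212; 0.18 adjusted over the list alone) and Pomc, the precursor of melanocortins, at 0.25 (SE 0.116; 0.269 adjusted over the list alone; list camera adjusted p = 0.731). edgeR's quasi-likelihood test called 7 of 18512 genes, 2 higher and 5 lower, and 2155 had an unadjusted p under 0.05. The count rested on single libraries, since it was 60 without KO replicate 3, 4 without WT replicate 2 and 3 without WT replicate 3, and DESeq2 called 80.

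In PGAT of cohort 2, a visceral fat depot whose response bears on metabolic health, genes of liver cells were lower in TIRR KO than in WT. Alb, the main plasma protein made by hepatocytes, was at 232 ± 189 CPM in KO and 1210 ± 713 CPM in WT (log2 fold change -2.39, SE 0.751), and Ttr, Apoc3 and Ahsg, which encode other secreted liver proteins, had log2 fold changes of -2.41, -2.29 and -2.40. Adjusted over the list alone, 8 of 10 hepatocyte genes passed, all lower, and none passed over all genes (camera adjusted p = 6.61e-09, and adjusted p = 0.598 with an estimated correlation). Genes of bile acid synthesis and transport had a median of -2.281 over 11 genes, with 9 passing adjusted over the list alone and none over all genes, among them Nr0b2 (-3.02, SE 0.761), Abcb11 (-2.45, SE 0.709) and Cyp8b1 (-2.45, SE 0.82; camera adjusted p = 1.54e-09, and adjusted p = 0.598 with an estimated correlation). Hepatocyte genes in these fat libraries stood at 2.68 ± 1.78% of their liver level in WT and 0.52 ± 0.44% in KO (n = 3 and 3).

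Immune and stress gene groups differed in both directions in the same fat, where the KO libraries stood apart from each other (chi-square per degree of freedom of 114.268 to 182.671 between them against 22.315 to 38.529 between WT libraries), KO replicate 2 the most. T and NK cell genes had a median of -0.488 over 12 genes, with Zap70, a kinase of the T cell receptor, at -1.07 (SE 0.47) and Cd3e at -1.15 (SE 0.581), and none passed singly (camera adjusted p = 0.000933, and adjusted p = 0.598 with an estimated correlation). B cell genes had a median of -0.826 over 10 genes, with Igkc, the kappa light chain, at -0.98 (SE 0.38), and none passed singly (camera adjusted p = 0.0121, and adjusted p = 0.924 with an estimated correlation). Macrophage genes had a median of 0.335 over 17 genes, with Cd163 at 0.52 (SE 0.289) and Adgre1 at 0.39 (SE 0.264), and none passed singly (camera adjusted p = 0.0195, and adjusted p = 0.924 with an estimated correlation). Immediate early genes were shifted upward over 12 genes, with Nr4a1 at 1.10 (SE 0.224) passing adjusted over the list alone and Fosb at 1.40 (SE 0.509) and Atf3 at 1.22 (SE 0.474) not passing (camera adjusted p = 7.14e-05, and adjusted p = 0.598 with an estimated correlation).

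None of 16 mature adipocyte genes passed in PGAT, with Lep, the satiety hormone leptin, at 0.62 (SE 0.574) and Pparg, the master regulator of adipocytes, at -0.31 (SE 0.238; camera adjusted p = 0.958). The p53 targets had a median of 0.163 over 49 genes, none passing singly, with Sesn1 at 0.35 (SE 0.151) and Pmaip1 at 0.74 (SE 0.332), while Gls2, which liver also expresses, was at -2.30 (SE 0.726; camera adjusted p = 0.0518, and adjusted p = 0.924 with an estimated correlation). Trp53 had a log2 fold change of -0.14 and Trp53bp1 of 0.04, each with an edgeR adjusted p = 1. edgeR called 1 of 16601 genes, Nudt16l1, which was lower, and 620 had an unadjusted p under 0.05. DESeq2 called 26, and leaving out any 1 of the 6 libraries gave 0 calls. In simulated data, edgeR recovered 23% of genes changed 2-fold and 89.9% of genes changed 4-fold. Each simulated gene had the same spread in both genotypes, taken from these libraries, and many genes were changed at once. The real KO libraries differed more among themselves than the WT libraries, so real recovery may be lower. Hepatocyte genes had a median log2 fold change of -2.336, beyond 4-fold, and none passed over all genes. Most 2-fold changes would therefore be missed by this test at this size. The 89.9% cannot be read as the share of real 4-fold changes found.

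In liver, the organ that handles lipid and glucose supply, circadian clock genes differed between TIRR KO and WT. Adjusted over the list alone, 11 of 18 were higher and 1 lower. The higher ones included Dbp (log2 fold change 3.75, SE 1.12), a clock output transcription factor, the repressor gene Ciart (3.18, SE 0.7), Per3 (2.26, SE 0.818) and Nr1d1 (1.20, SE 0.318), which encodes the nuclear receptor REV-ERB alpha. Cry1, a late-phase repressor of the clock, was lower (-1.11, SE 0.21), and the activator genes Npas2 (-1.58, SE 0.648) and Arntl (-1.12, SE 0.503) were at negative values that did not pass. No clock gene passed over all genes (camera adjusted p = 0.00445, and adjusted p = 0.719 with an estimated correlation). The sample annotation used here holds no hour of collection or feeding state. The clock differences, and the shifts in fatty acid genes below, therefore cannot be assigned to genotype alone.

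**Figure D2:**
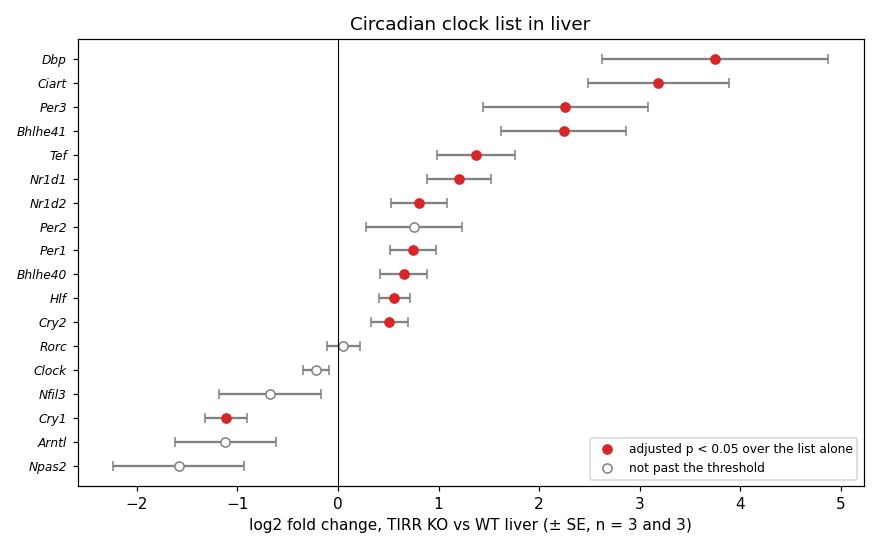
Log2 fold change (± SE) of 18 circadian clock genes, TIRR KO against WT liver (n = 3 and 3); filled points passed an adjusted p of 0.05 over the list alone. Dbp and Ciart stand at the positive end at 3.75 and 3.18, and Npas2, Arntl and Cry1 at the negative end.

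Genes of fatty acid oxidation and of PPAR alpha, the fasting-activated receptor that drives it, were shifted upward in KO liver with a median of 0.202 over 26 genes. Ppara was at 0.77 (SE 0.172), Cpt1a, which admits fatty acids to mitochondria, at 0.43 (SE 0.145) and Cyp4a14 at 4.11 (SE 1.272), and none passed singly (camera adjusted p = 0.00445, and adjusted p = 0.863 with an estimated correlation). In the lipolysis and lipid storage list, with a median of 0.407 over 15 genes, Pnpla2, the adipose triglyceride lipase, was higher at 0.62 (SE 0.12) adjusted over the list alone, and the droplet protein gene Plin5 was at 0.72 (SE 0.293) without passing (camera adjusted p = 0.0151, and adjusted p = 0.552 with an estimated correlation). Endothelial genes had a median of -0.305 over 8 genes, with Kdr, the receptor for VEGF, at -0.33 (SE 0.123), and none passed singly (camera adjusted p = 0.00445, and adjusted p = 0.552 with an estimated correlation). Other lists were shifted downward too: macrophage (median -0.366), mesothelial (-0.299), inflammatory cytokines and NF-kB (-0.354), interferon response (-0.193) and extracellular matrix (-0.17), with camera adjusted p-values from 0.0219 to 0.0413, 0.863 with an estimated correlation, and no gene passing singly or adjusted over its list alone.

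The p53 targets had a median of 0.115 over 43 genes in liver, none passing, with Gdf15, a stress-induced hormone, at 2.06 (SE 0.795; camera adjusted p = 0.439). Trp53 had a log2 fold change of -0.34 (edgeR adjusted p = 0.901) and Trp53bp1 one of 0.08 (edgeR adjusted p = 0.996). edgeR called 1 of 13871 genes, the long noncoding RNA Gm4316, which fell from 81.2 ± 29.2 to 7.94 ± 0.601 CPM (log2 fold change -3.35, SE 0.282; adjusted p = 0.0357), and 763 had an unadjusted p under 0.05. Gm10524 was at -2.49 (SE 0.252; edgeR adjusted p = 0.07) and Miga1, a mitochondrial fusion factor, at -2.08 (SE 0.257; edgeR adjusted p = 0.206). The count was 0 without WT replicate 1 or 2 or KO replicate 1 or 2 and 2 without KO replicate 3, and DESeq2 called 60. In simulated data with the spread of the liver libraries, edgeR recovered 59.7% of genes changed 2-fold.

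The TIRR effect was then compared between tissues by testing the difference itself. Against liver, the KO effect in PGAT was more negative for Nudt16l1 (difference of log2 fold changes -1.47, SE 0.23; edgeR adjusted p = 0.0464). It was more positive for Gm4316 (2.91, SE 0.312; edgeR adjusted p = 0.00094), Gm10524 (2.78, SE 0.304; edgeR adjusted p = 0.00094), Miga1 (2.08, SE 0.332; edgeR adjusted p = 0.0464) and Basp1, a membrane protein of growing neurites (2.37, SE 0.344; edgeR adjusted p = 0.0249). Bile acid genes, with a median difference of -2.265 over 11 genes and 10 passing adjusted over the list alone, and hepatocyte genes, with 6 of 10 passing adjusted over the list alone, had lower KO effects in PGAT than in liver (camera adjusted p = 1.66e-09 and 1.29e-06, and adjusted p = 0.442 and adjusted p = 0.379 with an estimated correlation). Hepatocyte genes stood at only 0.11% to 4.62% of their liver level in the fat libraries. Liver RNA in the fat may be the source, so these list differences cannot be assigned to a TIRR effect in fat. For PGAT against liver, edgeR called 5 genes of 21010, 4 of them more positive in PGAT, and 1533 had an unadjusted p under 0.05. With the animal as a block, as read from the codes shared across tissues, it called 2, Gm4316 and Gm10524. DESeq2 called 74, and the count was 0 without WT replicate 2, 3 without KO replicate 1 and 13 without KO replicate 2.

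Between liver and hypothalamus the KO effect was more negative in liver for Gm10524 (-3.03, SE 0.301; edgeR adjusted p = 0.000491), Gm4316 (-2.98, SE 0.316; edgeR adjusted p = 0.000576), Miga1 (-2.12, SE 0.319; edgeR adjusted p = 0.0383), AC158975.2 (-2.03, SE 0.317; edgeR adjusted p = 0.0437) and Plcd3, a phospholipase C (-2.57, SE 0.409; edgeR adjusted p = 0.0437). Circadian clock genes had higher KO effects in liver with a median difference of 0.663 over 18 genes, 4 higher and 1 lower adjusted over the list alone, among them Ciart (2.86, SE 0.729) and Cry1 (-0.93, SE 0.278; camera adjusted p = 0.00273, and adjusted p = 0.506 with an estimated correlation). These 5 genes were the calls among 21010, with 788 at an unadjusted p under 0.05, and the animal block left 2, Gm10524 and Gm4316. Leaving out WT replicate 1 or WT replicate 2 gave 2 calls, and DESeq2 called 15.

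Between PGAT and hypothalamus edgeR called 0 genes, with 1233 at an unadjusted p under 0.05, and DESeq2 called 28. With edgeR the count was 1 without KO replicate 1 and 2 without KO replicate 2. Cd59a had the smallest p (difference 1.45, SE 0.211; edgeR adjusted p = 0.0738). Immediate early genes had higher KO effects in PGAT with a median difference of 1.329 over 12 genes, of which 1, Junb (1.43, SE 0.382), passed adjusted over the list alone (camera adjusted p = 1.09e-05, and adjusted p = 0.437 with an estimated correlation). Of the genes that fell in hypothalamus and in PGAT, 1 was shared, the deleted gene Nudt16l1. No gene called in liver was also called in either of the other tissues.

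In MEFs, the comparison of TIRR KO with TIRR fl/fl asked what TIRR does where p53 is present. With all 12 libraries edgeR called 0 of 15709 genes, with 463 at an unadjusted p under 0.05, and DESeq2 called 249. The smallest adjusted p belonged to Des, the muscle intermediate filament gene desmin (log2 fold change -9.09, SE 1.046; edgeR adjusted p = 0.0784). All values that follow for MEFs come from the 9 libraries, of which fl/fl, TIRR KO and P53 KO had 2 each and P53 KO TIRR KO had 3. The labels do not say whether replicates of a genotype are separate lines. The spread of these libraries was small (a biological coefficient of variation of 0.055, against 0.102 in hypothalamus, 0.188 in liver and 0.291 in PGAT).

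Target genes of p53 rose in TIRR KO MEFs: 41 of 50 were higher and 3 lower, with the same counts adjusted over the list alone, and the median log2 fold change was 1.376 (camera adjusted p = 1.08e-10, and adjusted p = 0.109 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 27.8 ± 1.48 to 586 ± 11.2 CPM (log2 fold change 4.40, SE 0.068; edgeR adjusted p = 7.3e-17). Ccng1 rose by 3.74 (SE 0.07) and Mdm2, the ubiquitin ligase that restrains p53, rose by 2.65 (SE 0.062). Trp53 itself rose from 225 ± 9.22 to 332 ± 24.1 CPM (log2 fold change 0.56; edgeR adjusted p = 1.88e-06), while Trp53bp1 was at -0.02 (edgeR adjusted p = 0.824). Whether p53 was active in the fl/fl control is open, since the targets did not fall together from fl/fl to P53 KO (median -0.096). The rise of the targets therefore cannot be told apart from a difference in p53 activity between the lines.

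Extracellular matrix genes fell in the same comparison, 17 of 20 lower and 1 higher, with the same counts adjusted over the list alone (median -1.102; camera adjusted p = 6.52e-06, and adjusted p = 0.481 with an estimated correlation). Col1a1, a chain of type I collagen, fell by 1.64 (SE 0.052), Col3a1 by 1.88 (SE 0.076) and Postn, which encodes the matrix protein periostin, by 2.23 (SE 0.094). All 6 smooth muscle genes fell, over all genes and adjusted over the list alone, including Des (-9.45, SE 0.157), Cnn1 (-5.47, SE 0.099) and Tagln (-1.51, SE 0.078; camera adjusted p = 0.00132, and adjusted p = 0.245 with an estimated correlation). Glycolysis genes fell in 12 of 17 cases and rose in none, with the same counts adjusted over the list alone, including Aldoa (-1.25, SE 0.058) and Ldha, lactate dehydrogenase A (-1.10, SE 0.057; camera adjusted p = 0.0064, and adjusted p = 0.509 with an estimated correlation).

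Some genes had no counts in 1 of these groups. Tbx20, a cardiac transcription factor, was at least 1770-fold higher in TIRR KO than in fl/fl (floor of 3 counts over the group), and Ano3 was at least 512-fold higher. Pax2, a kidney and midbrain transcription factor, was at least 370-fold lower and Hoxb9, which marks position along the body axis, at least 500-fold lower. edgeR called 9110 of 14901 genes, 4496 higher and 4614 lower, and 2811 of the calls were at least 2-fold. With 2 libraries per group whose origin is not stated, these calls compare the cultures sampled, and differences between lines cannot be told from genotype.

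P53 KO was compared with TIRR fl/fl to see what p53 contributes where TIRR is present. Trp53 fell from 225 ± 9.22 to 38.7 ± 2.83 CPM (log2 fold change -2.54, SE 0.074; edgeR adjusted p = 2.74e-14). Its targets did not move together: of 50, 18 rose and 21 fell, with the same counts adjusted over the list alone (median -0.096; camera adjusted p = 0.91). Ephx1, an epoxide hydrolase gene, fell by 2.63 (SE 0.086), Phlda3 fell by 2.00 (SE 0.075) and Pmaip1, the death gene Noxa, fell by 2.02 (SE 0.109), while Cdkn1a rose by 0.99 (SE 0.066). The plot of p53 targets shows TIRR KO above the other 3 genotypes for each of the 5 targets drawn, and Trp53 far lower in both P53 KO genotypes.

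**Figure D3:**
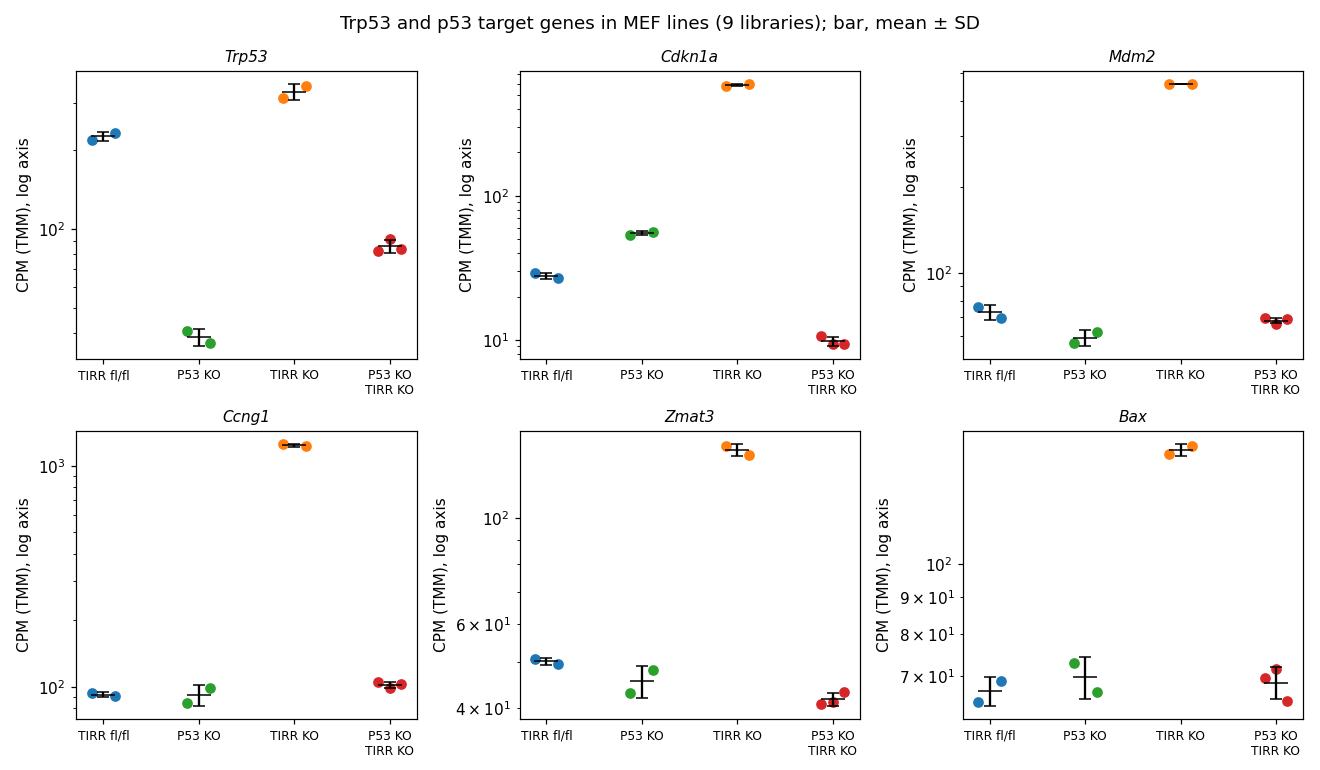
Trp53 and the p53 targets Cdkn1a, Mdm2, Ccng1, Zmat3 and Bax in CPM (log axis) per MEF library for 4 genotypes (9 libraries); each point is 1 library and the bars give mean ± SD. Cdkn1a stands at 586 CPM in TIRR KO and 27.8 CPM in TIRR fl/fl.

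All 20 extracellular matrix genes fell in P53 KO, over all genes and adjusted over the list alone, with Postn at -5.63 (SE 0.111) and Sparc, a collagen-binding matrix protein, at -2.59 (SE 0.054; camera adjusted p = 1.66e-09, and adjusted p = 0.702 with an estimated correlation). Genes of S phase and mitosis rose in 26 of 30 cases and fell in 1, with the same counts adjusted over the list alone, including the replication licensing genes Mcm5 (0.96, SE 0.048) and Mcm7 (0.79, SE 0.054; camera adjusted p = 0.000103, and adjusted p = 0.702 with an estimated correlation). Among the largest changes, Hoxd8 was at least 693-fold lower and Piezo2, a mechanosensitive channel gene, at least 443-fold lower in P53 KO, and Aim2, a sensor of cytosolic DNA, was at least 271-fold higher. Xist, expressed from the inactive X of female cells, ranged from 230 to 314 CPM in fl/fl and from 0.23 to 4.66 CPM in P53 KO, and the Y-linked Ddx3y was at most 0.29 and 59.6 to 67.6 CPM. edgeR called 9942 genes, 4985 higher and 4957 lower, and the contrast with p53 status is also a contrast of sex. With all 12 libraries it called 0, with 645 at an unadjusted p under 0.05, and DESeq2 called 416.

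P53 KO TIRR KO was compared with P53 KO to ask what TIRR does without p53. The p53 targets split, 18 higher and 23 lower of 50, or 18 and 24 adjusted over the list alone (median -0.173; camera adjusted p = 0.379). Cdkn1a fell by 2.49 (SE 0.064) and Tap1, a peptide transporter of antigen presentation, fell by 2.69 (SE 0.13), while Pmaip1 rose by 3.09 (SE 0.099). Reads on Trp53 rose from 38.7 ± 2.83 to 86 ± 4.91 CPM (edgeR adjusted p = 2.22e-10). Extracellular matrix genes rose, 16 of 20 higher and 2 lower, with the same counts adjusted over the list alone, among them Thbs1 (4.07, SE 0.104), Postn (3.71, SE 0.099) and Col1a1 (1.83, SE 0.049; camera adjusted p = 4.2e-05, and adjusted p = 0.563 with an estimated correlation).

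Cell cycle genes fell in 27 of 30 cases and rose in 1 when TIRR was absent from P53 KO cells, with the same counts adjusted over the list alone, including Mcm5 (-1.33, SE 0.043) and Mcm7 (-0.86, SE 0.048; camera adjusted p = 3.74e-06, and adjusted p = 0.563 with an estimated correlation). All 6 smooth muscle genes rose, over all genes and adjusted over the list alone, including Cnn1 (5.49, SE 0.102) and Tagln (3.39, SE 0.081; camera adjusted p = 0.00288, and adjusted p = 0.563 with an estimated correlation). Pou3f3, a neural and kidney transcription factor, was at least 1120-fold higher and Ifi202b, an interferon-inducible DNA sensor, at least 1320-fold lower. edgeR called 10491 genes, 5437 higher and 5054 lower. With all 12 libraries it called 0, with 902 at an unadjusted p under 0.05. DESeq2 called 728, and edgeR 392 when only these groups were in the fit.

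P53 KO TIRR KO was also compared with TIRR KO to ask what p53 contributes where TIRR is absent. The p53 targets fell in 42 of 50 cases and rose in 1, with the same counts adjusted over the list alone, led by Cdkn1a (-5.90, SE 0.064), Ccng1 (-3.60, SE 0.059), Ak1 (-3.19, SE 0.062) and Mdm2 (-2.74, SE 0.054; camera adjusted p = 3.22e-12, and adjusted p = 0.0816 with an estimated correlation). Cholesterol synthesis genes rose in 19 of 22 cases and fell in none, with the same counts adjusted over the list alone, including Pcsk9, which lowers LDL receptor levels (3.11, SE 0.121), and Dhcr24 (1.14, SE 0.055; camera adjusted p = 0.000517, and adjusted p = 0.332 with an estimated correlation). Six2, a nephron progenitor transcription factor, was at 96.8 ± 3.21 CPM against 0.0587 ± 0.083 CPM. Xist was at 475 ± 18.6 CPM in TIRR KO and 0.32 ± 0.309 CPM in P53 KO TIRR KO, so sex differs here too. edgeR called 9575 genes, 4962 higher and 4613 lower. With all 12 libraries it called 0, with 632 at an unadjusted p under 0.05, and DESeq2 called 461.

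The interaction asked whether the effect of TIRR loss depends on p53. Both groups with p53 express Xist and both P53 KO groups express Y-linked genes, so it is also a comparison of the TIRR effect between female and male cells. It also rests on the fl/fl libraries, and whether p53 was active in them is open. For p53 targets the effect of TIRR loss was lower without p53 in 39 of 50 cases and higher in 3, with the same counts adjusted over the list alone (median difference -1.288; camera adjusted p = 1.97e-07, and adjusted p = 0.255 with an estimated correlation). Cdkn1a differed by -6.89 (SE 0.092), Ccng1 by -3.59 (SE 0.089) and Mdm2 by -2.45 (SE 0.082). For all 20 extracellular matrix genes, over all genes and adjusted over the list alone, the effect was higher without p53, with Col1a1 at 3.47 (SE 0.071) and Postn at 5.94 (SE 0.136; camera adjusted p = 2.27e-08, and adjusted p = 0.388 with an estimated correlation). edgeR called 9945 genes, 5154 higher and 4791 lower. With all 12 libraries it called 0, with 774 at an unadjusted p under 0.05, and DESeq2 called 562.

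Genes that moved the same way on TIRR loss with and without p53 were about as many as independent lists would share, and opposite calls were more. Of 14901 genes, 1634 rose in both comparisons against 1640.48 expected for independent lists (Fisher's exact p = 0.602), and 1569 fell in both against 1564.94 (Fisher's exact p = 0.447). Opposite calls numbered 3643 against 3208.45. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.109 and a Spearman rho of -0.057. The comparisons share no library, and they differ in sex as well as in p53.

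For PGAT of cohort 1 and BAT, only the share of reads assigned to genes could be compared. It was 70.0 ± 1.37% in PGAT (n = 26) and 40.4 ± 2.39% in BAT (n = 26), where multi-mapping took 36.6 ± 2.09%. In BAT, mice that lack TIRR in adipocytes through AdipoQ-Cre had a share of 38.4 ± 1.93% against 41.2 ± 1.9% in TIRR fl/fl (n = 5 and 5; difference -2.86 percentage points; exact two-sided permutation p = 0.0476, adjusted p = 0.286 over 6 comparisons). That exact p was between 0.0476 and 0.103 when 1 mouse was left out, and above 0.05 without control replicates 2, 3 or 5 or AdipoQ-Cre replicates 2, 4 or 5. The other 5 exact permutation p-values were 0.349 to 0.929, with adjusted p = 0.9 or 0.929. These were TIRR KO against WT in PGAT (0.63 points, n = 4 and 3) and BAT (-2.49 points, n = 4 and 3), P53KO TIRR KO against P53KO control in PGAT (0.841 points, n = 5 and 5) and BAT (-0.063 points, n = 5 and 4), and AdipoQ-Cre in PGAT (0.232 points, n = 4 and 5). Single libraries carried these values: leaving out 1 gave -0.134 (without WT replicate 3) to 1.499 (without WT replicate 1) for TIRR KO in PGAT and -5.082 (without WT replicate 3) to 0.248 (without WT replicate 2) in BAT. For P53KO TIRR KO it gave 0.207 (without control replicate 1) to 1.215 in PGAT and -0.448 to 0.342 (without control replicates 3 and 4) in BAT, and for AdipoQ-Cre in PGAT -0.235 to 1.023 (without AdipoQ-Cre replicates 1 and 3). The smallest p the permutations could give was 0.0286 for 3 against 4 and 0.0079 for the others.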

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

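All tests in this part were chosen after the results were seen, except the tests of differences between tissues and the interaction with 12 libraries. The interaction with 9 was chosen after. The test of genotype labels on chromosome 16 was chosen after the deviating MEF libraries were seen. Only its prediction was written before its own value was seen. In MEFs, 3 libraries (TIRR fl/fl replicate 1, P53 KO replicate 3 and TIRR KO replicate 3) stood apart from the other 9. Lower depth did not account for this, since other libraries thinned to 4.3 M counts still correlated with their own genotype at r of 0.993 or more across genes while these 3 reached at most 0.106 (9755 genes chosen by their mean in the 9 libraries, where the negative r given above covers 9001 genes chosen by their mean over all 12; the bound of 0.5 for these 3 was set after the value was seen). A swap of labels among these 3 genotypes was also argued against, because on chromosome 16 all 3 deviated most like their own genotype (r of 0.78 to 0.884 over 290 genes, against -0.1 or lower for the others). P53 KO TIRR KO was not among the genotypes compared, so a library of that genotype under a wrong label was not tested for. Counting against shifted gene coordinates is a candidate explanation: genes whose counts matched the other libraries of the genotype were neighbours on the chromosomes, with 64.7% or more having a matching next neighbour against at most 10.0% in 1000 shuffles, and chromosome 16 matched at 68.6 to 69.8% against 5.8 to 6.2% over all genes. No biological explanation was tested.

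Hepatocyte genes were higher in WT than in KO perigonadal fat of cohort 2. Liver RNA in the fat libraries may be the source. In every fat library at least 8 of 10 hepatocyte genes stood within a factor of 2 of 1 common share of their liver level. That share, their median, ran from 0.11% to 4.62%. Alb stood at 0.133% to 4.58%, but it is among the 10 genes and so helps set that median. Whether TIRR genotype sets the share cannot be told apart from chance carry-over, because the KO shares lay below the WT shares in all libraries but the exact permutation p of 0.1 is the smallest that 3 against 3 can give. Bile acid genes were lower in KO fat too, with 9 of 11 passing adjusted over the list alone and none over all genes. Gls2 among the p53 targets was at a negative value that did not pass.

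The p53 targets did not fall together from TIRR fl/fl to P53 KO MEFs, with 18 higher and 21 lower of 50 in P53 KO. Mislabelled P53 KO cells were argued against, as Trp53 differed by a log2 fold change of -2.539. Loss of p53 function in the fl/fl line, which can arise when fibroblasts are immortalised by passaging, may explain it. The target list median of -0.096 is itself the pattern to be explained, so it lends this explanation no support. The explanation stays open, because members moved to both sides and the lines also differ in sex. The sex of the embryos cannot be told apart from p53 status, since 4 of 4 Y-linked genes differed between P53 KO and fl/fl. The nature of the replicates, which the labels leave open, was not tested.

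By a test of the difference itself, the TIRR effect differed for 5 genes in PGAT against liver and for 5 in liver against hypothalamus. In MEFs such a test between p53 backgrounds called 9945 genes with 9 libraries and 0 with all 12. The p53 backgrounds also differ in sex, and differences between lines cannot be told from genotype. With the animal as a block, 2 and 2 genes were left between tissues, Gm4316 and Gm10524 in both, and the call of Nudt16l1 was lost. Regrouping the 6 samples of a comparison gives 10 splits, too few for a share under 0.05. Real and highest other counts of called genes were 7 and 1 in hypothalamus, 1 and 0 in PGAT, 1 and 0 in liver, 5 and 2 for PGAT against liver, 5 and 0 for liver against hypothalamus, 0 and 2 for PGAT against hypothalamus, and 0 and 0 in each of 4 MEF contrasts with 12 libraries. Where the real count is 0, every split reaches it by construction (10 of 10, and 40 of 40 drawn for the interaction with 12 libraries), so those counts decide nothing. The highest other was 12352, from the only split that put all 3 deviating libraries in 1 group, which points to that structure of the samples.

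Total reads of single libraries stood apart from their groups in 5 cases. They were 2.45 M for BAT AdipoQ-Cre replicate 5, 53.47 M for BAT P53KO TIRR KO replicate 1 and 8.44 M for PGAT cohort 1 P53KO TIRR KO replicate 4. They were 51.71 M for PGAT cohort 1 P53KO control replicate 2 and 15.18 M for PGAT cohort 1 TIRR fl/fl replicate 3. The test covered 20 combinations of group and measure and marks about 1 in 20 by chance.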

How the results depend on the processing

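Leaving out the 3 deviating MEF libraries was chosen after seeing the data. Of the alternative values for whole comparisons, 205 kept their side of the threshold or stayed close, 66 moved and 7 weakened. Of those for named genes, 8683 kept direction and call, 225 weakened, 2 strengthened and 2 reversed. Most of the values that kept were from the MEF fits of 9 libraries, and genes that stayed uncalled also count as kept. Tissue calls held less well. Called under every alternative were 2 of 7 genes in hypothalamus, 0 of 1 in PGAT and 0 of 1 in liver. For the tissue differences it was 0 of 5 for PGAT against liver and 2 of 5 for liver against hypothalamus. Causes were not tested except where stated.

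With no filter on low counts, edgeR called 89 genes in hypothalamus, 2 in PGAT, 104 in liver, 25 for PGAT against liver, 1 for PGAT against hypothalamus and 10 for liver against hypothalamus. DESeq2's Wald test called 80, 26, 60, 74, 28 and 15 in that order. For the 12 MEF libraries it called 249 (TIRR KO against fl/fl), 416 (P53 KO against fl/fl), 728 (P53 KO TIRR KO against P53 KO), 461 (against TIRR KO) and 562 (interaction). limma called 20 in hypothalamus at either pseudocount, 0 in PGAT at log2(TPM + 1), and 11 and 8 in liver at log2(TPM + 1) and log2(TPM + 0.1). DESeq2 size factors gave 3 for PGAT against liver. With only its groups in the fit, P53 KO TIRR KO against P53 KO had 392 calls. Without the 3 deviating libraries, MEF calls rose from 0 to 9110, 9942, 10491, 9575 and 9945. With an estimated correlation, the number of lists past the threshold fell to 0 in all 11 comparisons, including the MEF fits of 9 libraries. At an adjusted p of 0.1, 2 genes fell in both PGAT and hypothalamus.

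The replicate block left 0 calls in PGAT, and for BAT AdipoQ-Cre against fl/fl the paired exact permutation gave -2.857 points with p = 0.125. Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.073 to 0.073 in hypothalamus, -0.368 to 0.367 in PGAT, -0.004 to 0.096 in liver and -0.088 to 0.04 in MEFs. The animal block gave 2 calls for PGAT against liver and 2 for liver against hypothalamus.

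Leaving out 1 replicate gave 3 to 60 calls in hypothalamus, 0 to 0 in PGAT, 0 to 2 in liver, 0 to 13 for PGAT against liver, 0 to 2 for PGAT against hypothalamus and 2 to 6 for liver against hypothalamus. The 12-library interaction gave 0 to 32, the 32 without TIRR fl/fl replicate 1. The BAT AdipoQ-Cre difference was -3.467 to -2.372 points. Without P53 KO replicate 2, which leaves P53 KO with 1 library, Stmn2 (P53 KO against fl/fl) reversed to -0.453 (2.419 without P53 KO replicate 1) and Xist (P53 KO TIRR KO against P53 KO) to 0.445 (-4.072 without P53 KO TIRR KO replicate 1), since their values differed between the P53 KO libraries.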

Other observations

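The list tests on hypothalamus and liver in this part were planned, those on the 9 MEF libraries were chosen after the results were seen, and so were the lists described. Beyond the groups already described, shifts in cell type and region genes were measured in KO hypothalamus. Oligodendrocyte and myelin genes had a median log2 fold change of -0.183 over 10 genes, with Mbp, a structural protein of myelin, at -0.27 (SE 0.105), and none passed singly (camera adjusted p = 0.000799, and adjusted p = 0.908 with an estimated correlation). Microglia genes had a median of -0.194 over 8, of which 3 passed adjusted over the list alone, including P2ry12 (-0.31, SE 0.075) and Cx3cr1 (-0.25, SE 0.075; camera adjusted p = 0.00461, and adjusted p = 0.908 with an estimated correlation). Genes of thalamus and neighbouring forebrain had a median of -0.331 over 10, with Calb2 at -0.37 (SE 0.1) passing adjusted over the list alone (camera adjusted p = 0.0334, and adjusted p = 0.908 with an estimated correlation). Extracellular matrix genes had a median of 0.285 over 18, with 3 passing adjusted over the list alone, led by Col4a2 (0.61, SE 0.145) of basement membranes (camera adjusted p = 0.0218, and adjusted p = 0.908 with an estimated correlation). In KO liver, the list of ATF4 and unfolded protein response genes did not pass as a group. Adjusted over the list alone, 1 of 14 was higher, Trib3 at 1.17 (SE 0.345), and 4 were lower, including Hspa5 at -0.71 (SE 0.105), Pdia4 at -0.46 (SE 0.124) and Dnajb9 at -0.73 (SE 0.216), and none passed over all genes (camera adjusted p = 0.087).

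In TIRR KO MEFs further groups moved against fl/fl (9 libraries). Mitochondrially encoded genes rose in 10 of 12 cases and fell in none, with the same counts adjusted over the list alone, including mt-Nd2 (0.91, SE 0.08) and mt-Co1 (0.92, SE 0.094; camera adjusted p = 0.00465, and adjusted p = 0.494 with an estimated correlation). Interferon response genes fell in 12 of 18 cases and rose in none, with the same counts adjusted over the list alone, including Cxcl10 (-2.06, SE 0.159) and Isg15 (-1.78, SE 0.149; camera adjusted p = 0.00651, and adjusted p = 0.372 with an estimated correlation). Inflammatory genes of the NF-kB pathway rose in 10 of 13 cases and fell in 2, with the same counts adjusted over the list alone, including Icam1 (5.50, SE 0.27) and Ccl7 (1.76, SE 0.078; camera adjusted p = 0.0101, and adjusted p = 0.438 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 22 cases and rose in 2, with the same counts adjusted over the list alone, with Pcsk9 at -4.05 (SE 0.123; camera adjusted p = 0.00767, and adjusted p = 0.494 with an estimated correlation).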
